A study of Mus musculus with 2 samples.

How the data were processed

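Prostate tissue of mice at postnatal day 35 was trimmed and enzymatically dissociated, and single cells were captured in droplets with 10x Genomics 3' v3 chemistry, per the labels' protocols. In this chemistry each captured RNA molecule carries a unique molecular identifier (UMI), and the reads come from near the 3' end of transcripts. There were 2 libraries, each of tissue from 2 mice per the series design text. The submitters' processing notes name Cell Ranger 3.1.0 and the genome build mm10. The annotation release and the filters on cells are not given in the sources used here. The deposited table holds raw UMI counts of 18994 genes in 14019 cells, with no normalization. It has an EGFP feature, a fluorescent reporter that the labels do not describe. A second deposited table gives the library and the authors' cluster number, from 0 to 18, for each cell, without names for the clusters. In both libraries each deposited cell had at least 751 genes with a UMI, and the highest mitochondrial share of a cell was 14.9% in one library and 15.0% in the other.

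Libraries were grouped by their titles, with 1 library titled ARKO and 1 titled Ctrl. The library names in the authors' table of cells follow the titles (ARKO and WT). The genotype field of the labels runs the other way: it calls the library titled ARKO normal and gives the Ar knockout for the library titled Ctrl. The text therefore writes of the library titled ARKO (or ARKO) and the library titled Ctrl (or Ctrl), and each direction given rests on the titles.

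The marker lists used to name the authors' clusters were fixed before the data were examined, as were the gene lists, the rule for named genes and most of the alternatives. The names themselves were not. The first choice of name for a cluster was the marker list with the highest median fold over other clusters among lists with at least 3 detected members, and names were then set by hand with regard to the 10 leading genes. Clusters 0 and 12 were basal-like, clusters 1, 2 and 7 fibroblast-like, clusters 4 and 5 smooth-muscle-like, cluster 9 seminal-vesicle-like, cluster 10 myeloid-like, clusters 11 and 16 T- or NK-like, cluster 13 endothelial-like and cluster 15 pericyte-like. Cluster 2 had 0 fibroblast markers among its 10 leading genes and was named because all 10 were detected, with a median log2 fold of 1.93 over other clusters. Cluster 3 had 9 of 11 luminal markers detected, with a median log2 fold of 0.58 and 0 among its leading genes. Its leading genes held 1 urothelial marker, Upk3a, and 3 of 5 urothelial markers were detected, with a median log2 fold of 0.46. Counting cluster 3 as prostate epithelial is therefore a choice. Cluster 6 had all 7 proximal luminal markers detected, with a median log2 fold of 2.66, and 1 proximal luminal and 1 luminal marker among its leading genes. Both were kept by number as a choice made after their markers were seen, since luminal and proximal luminal names would rest on mixed or weak leading genes. Clusters 8 (epithelial) and 14 (stromal) were led by cell cycle genes, cluster 17 was an unnamed epithelial cluster, and cluster 18 held smooth muscle genes with basal keratins. Lineage shares count clusters 0, 3, 6, 8, 12 and 17 as prostate epithelial and clusters 1, 2, 4, 5, 7, 14 and 15 as stromal. The main classes were fibroblast-like, smooth-muscle-like and basal-like cells and clusters 3 and 6. Leading genes were taken over both libraries pooled. Some of them differed in level between the libraries, such as Sbp in cluster 6, Acta1 in smooth-muscle-like cells and Aqp3 in basal-like cells. Sizes of clusters are therefore given as a description and are not read as numbers of a fixed cell type.

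UMI counts were summed over the cells of a class in each library and divided by the UMI total of the class, on the usual CPM scale. With 1 library per group no test was run and no p-value is given. UMI sums carry exact Poisson 95% intervals, shares of cells exact Clopper-Pearson 95% intervals, and ratios of ARKO over Ctrl conditional exact 95% intervals. All of these cover counting error only, not the spread between mice or preparations. UMI and ratio intervals treat each UMI as independent, so they also leave out the spread between cells. They are too narrow for genes whose UMIs lay largely in few cells. Log2 ratios, and ratios given under an alternative setting, used a prior of 0.5 UMI. A list member with at least 20 UMIs over both libraries was measured, and it counts as higher or lower where its ratio was at least 1.5-fold in either direction and its interval left out 1. The median log2 ratio of a list was set among those of 10000 random lists of the same size matched on mean expression, and the percentile is a description of these libraries. Dividing by the class total left the median gene of the class at a log2 ratio of −0.11 in fibroblast-like cells and −0.19 in cluster 6, against 0.09, 0.07 and −0.07 in smooth-muscle-like cells, basal-like cells and cluster 3. List medians are therefore given relative to the median gene of the class unless said to be before subtraction, values under an alternative are before subtraction, and percentiles are those of the list itself.

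The 20 lists were hedgehog targets, hedgehog ligands and pathway parts, the insulin-like growth factor axis, steroid receptors and androgen metabolism, androgen response, prostate secretory products, proliferation, extracellular matrix, smooth muscle contractile genes, Wnt, fibroblast growth factor, transforming growth factor beta and bone morphogenetic protein, Notch, dissociation stress, interferon response, chemokines with cytokines and complement, antigen presentation, basal and proximal keratins with progenitor markers, ribosomal proteins and mitochondrially encoded genes. Members of the first 3 lists and Ar could be named freely. From other lists the 2 to 4 members with the largest ratios in either direction among those with at least 50 UMIs were named. In each main class the rule also took the 10 genes highest in ARKO and the 10 highest in Ctrl, ranked by the interval bound nearest to 1. These had at least 50 UMIs, a UMI in at least 5% of the cells of either library, and a CPM of at least 0.2 of the gene's highest CPM in another class of that library. Mitochondrial, ribosomal, haemoglobin, predicted, Xist and Y-linked genes were not ranked. Genes named outside the rule are said to be so.

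For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. No cells were removed as doublets in the main values. Scrublet, run per library in scanpy 1.11.5, called 57 of 6871 ARKO cells (0.830%) and 91 of 7148 Ctrl cells (1.27%). Its score thresholds differed, at 0.376 in ARKO and 0.259 in Ctrl, so these rates are not on 1 scale. An alternative left out the top 5% of scores of each library. Other alternatives used a median-of-ratios size factor, a total without mitochondrial, ribosomal, haemoglobin and secretory genes, the mean over cells of each cell's CPM, cells without the top 10% by mitochondrial share, thinned cells, other UMI minimums, and new clusters of the cells. The new clusters used 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 1 (leidenalg 0.10.2), at this setting alone and with no integration of the libraries. They took the class with the highest mean log2 fold of its markers, and their epithelial list added Krt19 and Cdh1 to 5 of the fixed luminal markers.

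The steps were tested on simulated counts with 200 genes changed, drawn as Poisson counts from the sums of each main class. The intervals assume such counts, so their coverage was largely set in advance and checks the calculation only. Real UMIs can cluster in few cells, which the draw leaves out. The shares below are therefore not error rates for the real data. For fibroblast-like cells (11121 genes), smooth-muscle-like cells (10292), basal-like cells (10413), cluster 3 (11509) and cluster 6 (10798), the intervals held the true ratio for 95.6%, 95.7%, 95.9%, 95.7% and 95.9% of genes. The size rule recovered 49.3%, 61.2%, 49.3%, 46.3% and 49.3% of genes changed 1.5-fold and 94.0%, 94.0%, 97.0%, 98.5% and 97.0% of those changed 2-fold. It took 1.13%, 1.18%, 0.822%, 0.699% and 0.698% of unchanged genes as different. Positions come from GENCODE vM21 on mm10, in which 18325 of the 18994 symbols (96.5%) were found. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.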

Results

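The series title places the study in stromal androgen and hedgehog signalling of the pubertal prostate. Single-cell RNA was measured in 2 mouse prostate libraries of postnatal day 35, titled ARKO and Ctrl, both with Gli1 in the title. Ar encodes the androgen receptor, and Gli1 is a transcription factor and target gene of the hedgehog pathway. The genotype field gives the Ar knockout in Gli1-expressing cells for the library titled Ctrl, against the titles, and all directions given follow the titles. The library titled ARKO held 6871 cells and 60523105 UMIs, with a median of 4970 UMIs per cell (1102 to 129504). The library titled Ctrl held 7148 cells and 103007570 UMIs, with a median of 7596 UMIs per cell (1197 to 167255). The median mitochondrial share of a cell's UMIs was 3.55% in ARKO and 5.89% in Ctrl. With 1 library per group no difference between them has a replicate check, and the intervals given cover counting error only.

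Ar, the targeted gene, was lower in both stromal classes of the library titled ARKO. In fibroblast-like cells Ar stood at 96.7 CPM in ARKO (1293 UMIs, interval 1223 to 1365) and 194 CPM in Ctrl (1163 UMIs, 1097 to 1232), a ratio of 0.498 (0.460 to 0.539). In smooth-muscle-like cells it stood at 74.1 CPM in ARKO (524 UMIs, 480 to 571) and 168 CPM in Ctrl (1212 UMIs, 1145 to 1282), a ratio of 0.441 (0.397 to 0.489). Pericyte-like cells had a ratio of 0.494 (0.256 to 0.949). Outside the stroma, myeloid-like cells had 5 Ar UMIs in ARKO and 22 in Ctrl, a ratio of 0.242 (0.0716 to 0.655). T- or NK-like and endothelial-like cells had ratios of 1.05 (0.542 to 2.01) and 1.43 (0.764 to 2.66). The few myeloid-like UMIs, at 4.28 CPM in ARKO and 17.7 CPM in Ctrl, lay below the 24.3 and 23.3 CPM of T- or NK-like cells. They therefore do not show a lower Ar outside the stroma. Epithelial Ar ratios were 1.23 (1.11 to 1.36) in basal-like cells, 1.19 (1.11 to 1.27) in cluster 3 and 0.763 (0.706 to 0.825) in cluster 6. They were 1.60 (1.37 to 1.86) in cluster 8 and 0.823 (0.506 to 1.31) in cluster 17. The cluster 6 log2 ratio of −0.39 was −0.19 with a median-of-ratios size factor. The Ar ratio was 0.435, 0.564 and 0.501 in the fibroblast-like clusters 1, 2 and 7, and 0.686 and 0.327 in the smooth-muscle-like clusters 4 and 5. Cluster 4 held 58.2% of the smooth-muscle-like cells in ARKO and 44.1% in Ctrl, and cluster 5 held 41.8% and 55.9%.

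At 2000 UMIs per cell, an Ar UMI was present in 16.2% of ARKO fibroblast-like cells (14.9% to 17.7%, 126 shallower cells left out) and in 32.6% of those of Ctrl (29.9% to 35.4%, 75 left out). Among smooth-muscle-like cells the shares were 12.5% in ARKO (10.8% to 14.4%, 70 left out) and 29.2% in Ctrl (26.3% to 32.2%, 29 left out). Without thinning, Ar was seen in 30.1% and 52.9% of fibroblast-like cells and in 26.7% and 61.3% of smooth-muscle-like cells. T- or NK-like cells, taken as a class that should lack Ar, had a thinned share of 3.92% in ARKO and 3.55% in Ctrl, and unthinned shares of 7.45% and 7.01%. This class is not a clean background, here or below. In ARKO its Ar stood at 24.3 CPM (14.9 to 37.6), against 4.28 CPM (1.39 to 10.0) in myeloid-like cells. Actg2, a smooth muscle gene, stood at 75.4 against 3.43 CPM, and the 276 EGFP UMIs of the class lay in 20 of 161 cells. Whether stromal cells were mixed in was not tested. Median depths in ARKO and Ctrl were 4242.5 and 4503 UMIs in fibroblast-like, 4577 and 6734 in smooth-muscle-like and 4206 and 3588 in T- or NK-like cells. Ar lies on chromosome X from 98148769 to 98323215, on the plus strand (mm10, GENCODE vM21). The labels do not name the deleted part of Ar, and a 3' tag outside that part need not report the deletion.

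EGFP and Gli1 were both seen in the stroma of each library. EGFP stood at 2952 CPM in ARKO and 2717 CPM in Ctrl fibroblast-like cells, and at 5275 and 4111 CPM in smooth-muscle-like cells. It stood at 118 and 53.7 CPM in basal-like cells and at 336 and 93.0 CPM in T- or NK-like cells. Among fibroblast-like cells with at least 3 EGFP UMIs the Ar ratio was 0.474 (0.425 to 0.529), and among those with none it was 0.508 (0.443 to 0.583). The corresponding smooth-muscle-like ratios were 0.426 (0.379 to 0.479) and 0.443 (0.337 to 0.577). Gli1, on chromosome 10 from 127329882 to 127341974 on the minus strand, had 5 UMIs in basal-like cells of each library.

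**Figure D1:**
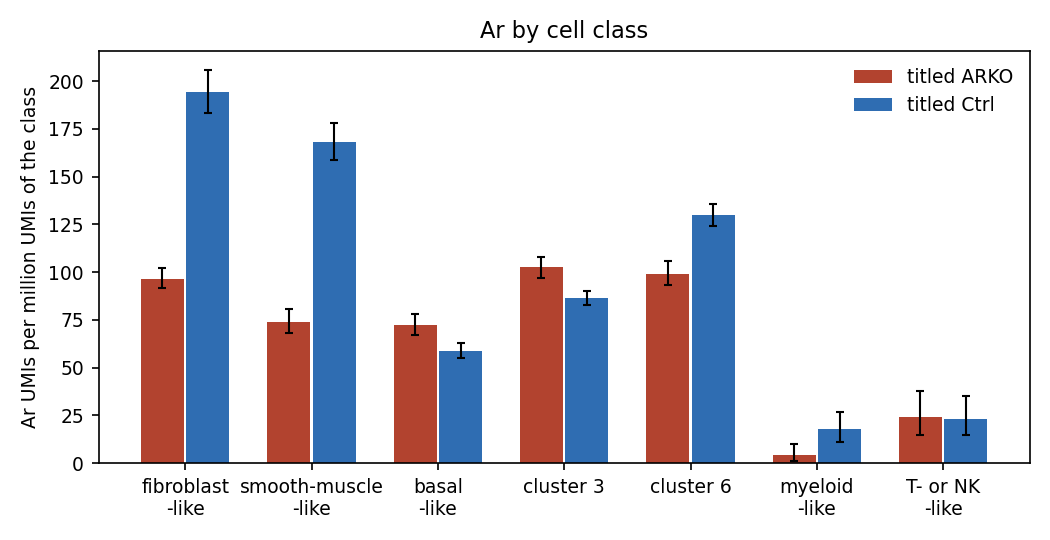
Ar level by cell class, with bars giving Ar CPM of the class in the libraries titled ARKO and Ctrl and error bars giving exact Poisson 95% intervals (counting error only). The fibroblast-like and smooth-muscle-like bars stand at 96.7 and 74.1 CPM in ARKO and at 194 and 168 CPM in Ctrl.

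The mix of cells differed between the libraries. Prostate epithelial cells made up 31.3% of ARKO cells (30.2% to 32.4%) and 52.9% of Ctrl cells (51.8% to 54.1%). Stromal cells made up 61.8% (60.6% to 62.9%) and 33.7% (32.6% to 34.8%). Basal-like cells were 20.1% and 20.6% of all cells, and 64.1% (62.1% to 66.2%) and 38.9% (37.3% to 40.5%) of the prostate epithelial cells. The epithelial difference lay mostly in clusters 3 (5.75% and 16.1% of all cells), 6 (4.38% and 8.07%) and 8 (0.728% and 6.90%). The basal-like share of the epithelium therefore follows the sizes of these clusters. Fibroblast-like cells made up 64.9% of ARKO and 51.2% of Ctrl stromal cells, and smooth-muscle-like cells 32.7% and 41.3%. Seminal-vesicle-like cells, with secretory genes of the neighbouring gland, were 0.815% (0.616% to 1.06%) and 5.67% (5.14% to 6.23%) of all cells. Leucocytes were 4.42% and 5.34% and endothelial-like cells 1.02% and 1.64%. Outside the seminal-vesicle-like cluster the epithelial shares were 31.6% and 56.1% and the stromal shares 62.3% and 35.7%. The tissue was trimmed and dissociated before capture, cells under 751 genes were absent, and ARKO had the lower median depth. By class the depth ran both ways. ARKO cells were deeper in clusters 3 (23768 against 15538 UMIs), 6 (26256 against 20175) and 8 (30125.5 against 17913). They were shallower in basal-like cells (5140 against 7380) and smooth-muscle-like cells (4577 against 6734), and slightly so in fibroblast-like cells (4242.5 against 4503).

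**Figure D2:**
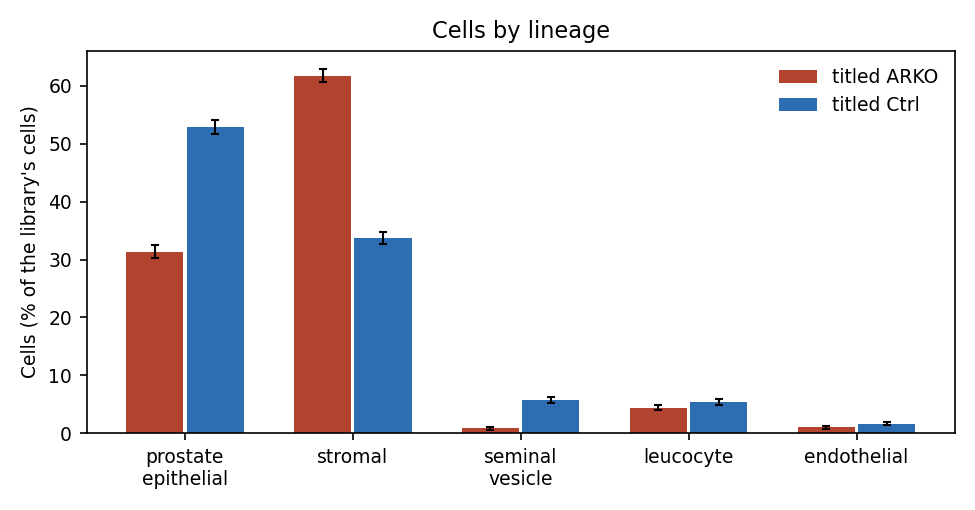
Cells by lineage, with bars giving the share of a library's cells in percent and error bars giving exact binomial 95% intervals (counting error only). Stromal cells were 61.8% of the library titled ARKO and 33.7% of the library titled Ctrl, and prostate epithelial cells 31.3% and 52.9%.

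Mki67, a marker of cycling cells, was lower in ARKO in epithelium, stroma and T- or NK-like cells. The ratio of its CPM was 0.252 (0.222 to 0.284) in prostate epithelial cells, 0.122 (0.0957 to 0.153) in stromal cells and 0.217 (0.118 to 0.372) in T- or NK-like cells. Myeloid-like cells had 1.24 (0.897 to 1.71). Top2a, which encodes a topoisomerase of dividing cells, had ratios of 0.266, 0.121, 0.437 and 1.02 in the same order. At 2000 UMIs per cell, Mki67 was present in 0.668% of ARKO (0.366% to 1.12%) and 4.17% of Ctrl (3.54% to 4.87%) epithelial cells. Among stromal cells it was present in 0.323% (0.172% to 0.552%) and 3.70% (2.97% to 4.56%). Thinning left out 56 ARKO and 135 Ctrl epithelial cells and 221 and 113 stromal cells, and the unthinned shares were 3.39% and 17.4% in epithelium and 0.660% and 6.22% in stroma. Endothelial-like cells had 1 Mki67 UMI in ARKO and 96 in Ctrl, a ratio of 0.0162 (0.000407 to 0.0927). With thinned cells the Mki67 ratio was 0.191 in epithelium and 0.0829 in stroma. Shares of thinned cells with 2 or more UMIs of the whole proliferation list were as follows: 28.7% in ARKO and 39.4% in Ctrl epithelium, 14.5% and 17.4% in stroma, 24.1% and 36.1% in myeloid-like cells, 19.7% and 40.2% in endothelial-like cells and 56.9% and 58.9% in T- or NK-like cells. Intervals of the 2 libraries overlapped in these last 3. The CPM ratio of that list was 0.770 (0.717 to 0.828) in myeloid-like cells and 0.455 (0.448 to 0.463) in epithelium. No class here can be taken to lack Mki67, so no background share is given.

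Proliferation genes were lower in ARKO within 4 of the 5 main classes. Of 21 measured members 15 were lower in fibroblast-like cells and 14 in basal-like cells, with 0 higher, and of 22 members 18 were lower in cluster 3 and 21 in cluster 6, with 0 higher. Medians lay at −1.09, −1.37, −1.48 and −1.76 relative to the median gene, below all 10000 random lists. In cluster 3 Mki67 stood at 0.0586, in basal-like cells Cenpf at 0.116 and in cluster 6 Tpx2 at 0.0400. Smooth-muscle-like cells had 3 members higher (Stmn1 2.12, Hmgb2 1.95 and Mcm4 1.88) and 3 lower of 18, and a median of −0.40 at percentile 0.78. That median of −0.30 before subtraction turned to 0.0498 with each cell thinned and to 0.37 with members of at least 100 UMIs. The basal-like median of −1.30 before subtraction was −0.39 with each cell thinned and −0.53 with members of at least 100 UMIs. With the cycling stromal cluster 14 added, the fibroblast-like median of −1.20 before subtraction became −3.38.

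In fibroblast-like cells (2754 in ARKO and 1235 in Ctrl, with 13376244 and 5990487 UMIs), the insulin-like growth factor axis held both higher and lower genes. Igfbp3, which encodes a secreted binding protein of these growth factors (chromosome 11, 7206086 to 7213923, minus strand), stood at 5839 CPM in ARKO and 1639 CPM in Ctrl, a ratio of 3.56 (3.49 to 3.64). Igf2 (2.74), Igfbp6 (1.75), the receptor gene Igf1r (1.61) and the insulin receptor gene Insr (1.57) were also higher. The growth factor gene Igf1 stood at 475 and 802 CPM (0.593, 0.571 to 0.616), and Igfbp5 (0.600) and Igfbp2 (0.0746) were lower too. Of the Igfbp2 UMIs in Ctrl, 39.1% lay in 3 cells. These 5 higher and 3 lower genes were among 13 measured, and the median lay 0.51 above the median gene at percentile 99.98. Igfbp3 also leads clusters 1 and 2. Clusters 1, 2 and 7 held 39.2%, 38.8% and 22.0% of the fibroblast-like cells in ARKO and 42.3%, 38.7% and 18.9% in Ctrl. Of 13 new clusters of fibroblast or smooth muscle cells, made without integration, 8 had at least 90% of their cells from 1 library. A different mix of cell states within a class is therefore not separated from a difference within a state.

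Matrix genes were mostly lower in ARKO fibroblast-like cells. Of 25 measured, 14 were lower, such as Col15a1 and Col6a3 (both 0.316), and 3 were higher, the proteoglycan genes Dcn (2.33) and Lum (2.17) and the collagen gene Col14a1 (1.95). The median lay at −0.56, below all random lists. Col15a1 also leads cluster 2, and Lum and Col14a1 lead cluster 7. Smooth muscle contractile genes (8 of 15 lower and 0 higher, Actg2 0.165) lay at −0.55. Actg2, which also leads cluster 4, stood at 8.0 and 48.6 CPM, against 75.4 and 63.4 CPM in T- or NK-like cells, 3.43 and 24.1 CPM in myeloid-like cells and 1375 and 5089 CPM in smooth-muscle-like cells. The list was also lower in clusters 3 (7 of 15 members) and 6 (12 of 15), but basal-like cells had 3 higher and 1 lower of 15 (percentile 70.0). The source of this RNA in fibroblast-like cells was not tested. Fibroblast growth factor genes (8 of 15 lower and 0 higher, with Etv4 0.133, Fgfr2 0.377 and Dusp6 0.415) lay at −0.61. Interferon response genes (8 of 16 lower and 0 higher, with Rsad2 0.0947, Ifit1 0.263 and Ifit3 0.333) lay at −0.46. These 3 medians were also below all random lists. Without the top 10% of cells by mitochondrial share the contractile median of −0.66 before subtraction became −0.43, and with cluster 14 it became −1.17.

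Steroid and androgen genes of fibroblast-like cells differed in single members. Srd5a2, whose enzyme converts testosterone to dihydrotestosterone, stood at a ratio of 0.0534 (0.0276 to 0.0952), and the progesterone receptor gene Pgr at 1.88. Of 10 steroid receptor and androgen metabolism genes 1 was higher and 3 were lower (median −0.25, percentile 7.2). Of 91 androgen response genes 6 were higher (Zbtb16 3.09, Hpgd 2.09) and 14 lower (Dhcr24 0.202, Fkbp5 0.434), with a median of −0.04 at percentile 37.1. Wnt genes had 3 higher (Sfrp4 7.01, Rspo1 3.42) and 8 lower (Lgr5 0.285) of 21, at percentile 26.4. The transforming growth factor beta and bone morphogenetic protein list had 2 higher (Nog 3.61) and 5 lower (Bmp2 0.290, Gdf10 0.461) of 23, at percentile 45.5. Notch genes had 0 higher and 2 lower of 10 (Hes1 0.552), at percentile 8.84.

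Chemokine, cytokine and complement genes had 5 higher and 2 lower of 16 in fibroblast-like cells, with C3 at 2.51, Ccl11 at 2.35 and Cxcl13 at 0.513, all of which also lead cluster 7 (percentile 87.7). Antigen presentation genes had 3 higher and 0 lower of 9, with Cd74 at 4.01 and H2-Aa at 3.35 (percentile 86.6). Both also lead the myeloid-like cluster 10. Cd74 stood at 123 and 30.7 CPM here, 57.2 and 173 CPM in T- or NK-like cells, 11.7 and 15.3 CPM in smooth-muscle-like cells and 17.9 and 22.4 CPM in basal-like cells. Whether fibroblast-like cells or other cells are its source was not tested. Keratin and progenitor genes had 1 higher and 6 lower of 14 (percentile 3), and prostate secretory genes 1 higher and 3 lower of 6 (percentile 3.68). List members were not filtered for free RNA. The secretory gene Sbp stood at 4.26 and 28.7 CPM here, 6.85 and 28.1 CPM in myeloid-like cells and 3057 and 7134 CPM in cluster 6. The source of the RNA of these 2 lists was not tested. Ribosomal protein genes had 9 higher and 0 lower of 80, with a median of 0.32 at percentile 99.99. Dissociation stress genes had 5 higher and 0 lower of 20, with Hspa1b at 2.01, Btg2 at 1.67 and Fos at 1.55, and a median of 0.46 at percentile 99.93. Mitochondrially encoded genes had 9 lower and 1 higher of 13, with mt-Co3 at 0.457 and a median of −0.65, below all random lists.

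The 10 top-ranked genes higher in ARKO fibroblast-like cells included the Wnt-binding protein gene Sfrp4 (5.65 to 8.80), the prostaglandin F receptor gene Ptgfr (6.40), the leptin receptor gene Lepr (4.91), Dlk1 (4.05) and the glypican gene Gpc3 (3.59). Fmo5 (5.40), Galnt15 (5.0), Ms4a4d (4.07) and Pcolce2 (3.67) completed the set with Igfbp3. Dlk1 also leads cluster 1 and Pcolce2 cluster 7. Those lower in ARKO included Susd3 (0.0474), the fibrillin gene Fbn2 (0.0725), the alkaline phosphatase gene Alpl (0.0926), Col7a1 (0.115), Col4a3 (0.135), Scube2 (0.137) and Srd5a2. Mt3 (0.0523), Uchl1 (0.130) and the chemokine gene Cxcl9 (0.156) were lower too, with 42.2%, 87.5% and 29.3% of their Ctrl UMIs in 3 cells. The Uchl1 difference was not seen with new clusters of the cells (log2 ratio 0.0253), and with each cell thinned the ratios of Uchl1, Mt3 and Susd3 were 0.453, 0.125 and 0.0907.

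Hedgehog targets were mostly higher in ARKO smooth-muscle-like cells (1387 and 995 cells, with 7067676 and 7203780 UMIs). Gli1 stood at 16.7 CPM in ARKO (118 UMIs) and 8.05 CPM in Ctrl (58 UMIs), a ratio of 2.07 (1.5 to 2.89). The receptor genes Ptch1 (chromosome 13, 63508328 to 63573598, minus strand) and Ptch2 stood at 1.82 (1.56 to 2.14) and 2.04 (1.16 to 3.68), and the transcription factor gene Foxf1 at 2.29 (1.85 to 2.85). Of 10 measured targets 7 were higher, and 1, the hedgehog-binding inhibitor Hhip, was lower (0.548, 0.470 to 0.637). The median lay 0.67 above the median gene at percentile 99.91. Among 11 ligands and pathway parts, Gli2 (2.18), Evc (1.72) and Evc2 (1.61) were higher and Gas1 (0.628) was lower, with a median of −0.04 at percentile 39.5.

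In fibroblast-like cells the hedgehog targets had 1 member higher, Ptch2 (1.62, 1.19 to 2.24), and 2 lower, Foxf2 (0.535) and Mycn (0.164), of 11. Gli1 stood at 23.1 and 18.2 CPM (1.27, 1.02 to 1.59), with 1.38 (0.970 to 1.99) in cluster 1, 1.78 (1.18 to 2.73) in cluster 2 and 0.760 (0.501 to 1.18) in cluster 7. Ptch1 stood at 1.25 (1.05 to 1.49) and Hhip at 1.39 (1.09 to 1.78). The list's median was 0.36 (percentile 99.29), and before subtraction the median was 0.25 and the mean −0.17. Of 12 ligands and pathway parts Cdon (2.78) was higher and Hhat (0.535) lower, with a median of 0.27 at percentile 96. Before subtraction that median was 0.17, and it was −0.12 with each cell thinned. Whether the 2 classes differed in hedgehog genes was not tested.

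Contractile genes were lower in ARKO smooth-muscle-like cells. Of 15 measured, 12 were lower and 0 higher, with the smooth muscle actin gene Actg2 at 1375 and 5089 CPM (0.270, 0.264 to 0.276), Tpm2 at 0.387, Mylk at 0.455 and Myl9 at 0.516. The median lay at −0.84 at percentile 0.005. Actg2, Tpm2 and Mylk also lead cluster 4 and Myl9 cluster 5. The 4 lower members that lead neither cluster, chosen after their values were seen, were Flna (0.546), Smtn (0.578), Cald1 (0.600) and Synm (0.603). Among the top-ranked lower genes, the actin gene Acta1, also a leading gene of cluster 4, stood at 224 and 5238 CPM (0.0428), Tnnc2 at 0.103 and Ckm at 0.105. All are in the fixed skeletal muscle marker list. In cluster 4, 3 of its 5 members were detected, with a median log2 fold of 3.91, against 4.18 for smooth muscle markers. Whether skeletal muscle was a source of this RNA was not tested. Contractile genes were also lower in 12 of 15 members in cluster 6 and 7 of 15 in cluster 3, both epithelial. Basal-like cells had 3 higher and 1 lower of 15 (percentile 70.0). The cluster 6 median of −1.26 before subtraction was −0.59 without likely doublets, and the cluster 3 median of −0.53 was 0.0552 with each cell thinned.

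The insulin-like growth factor axis of smooth-muscle-like cells had 6 members higher and 2 lower of 13. Igfbp3 stood at 381 and 36.2 CPM (10.5, 9.25 to 11.98), with the Ctrl level no higher than in T- or NK-like cells. Igfbp6 stood at 1222 and 284 CPM (4.30), Igfbp4 at 2.75 and Igf1r at 2.38, while Igfbp2 (0.207) and Igfbp5 (0.502) were lower. The median lay 0.35 above the median gene at percentile 98.6. In T- or NK-like cells Igfbp3 stood at 181 CPM in ARKO and 37.0 CPM in Ctrl. Its smooth-muscle-like CPM was under 0.2 of that of fibroblast-like cells, so the rule for free RNA left it unranked, and the size of its ratio is uncertain. With new clusters of the cells that ratio was 6.18.

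Among steroid genes of smooth-muscle-like cells, Pgr had 118 UMIs in ARKO and 9 in Ctrl (13.4, 6.81 to 29.9), and the mineralocorticoid receptor gene Nr3c2 (3.42) and Srd5a1 (2.34) were higher. With Srd5a2 (0.392), 2 were lower and 4 higher of 10, and the median lay 0.60 above the median gene at percentile 99.41. Before subtraction that median was 0.69, and it was −0.30 with each cell thinned and −0.21 with members of at least 100 UMIs. Androgen response genes had 20 higher (Gucy1a3 4.16, Dnajb9 2.85) and 13 lower (Hpgd 0.348) of 91, with a median of −0.12 (percentile 8.75), and before subtraction a median of −0.03 and a mean of 0.04. Matrix genes had 11 lower (Col6a3 0.255, Col1a1 0.430) and 3 higher (Fbln2 2.79) of 25, with a median of −0.45 at percentile 0.06. Keratin and progenitor genes had 6 lower (Ly6a 0.0433) and 0 higher of 10, with a median of −0.90 below all random lists, or a log2 median of 0.0396 before subtraction with new clusters. Members of this list were not filtered for free RNA, and the source of their RNA was not tested.

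Wnt genes of smooth-muscle-like cells had 7 higher (Notum 4.53, Sfrp4 4.25) and 4 lower (Lgr5 0.232, Wif1 0.383) of 19. The transforming growth factor beta and bone morphogenetic protein list had 6 higher (Serpine1 3.88) and 4 lower (Grem2 0.139, Id2 0.387) of 22, with a median of 0.21, and before subtraction a median of 0.31 and a mean of −0.01. The latter median was −0.12 with new clusters and −0.10 with cluster 18 added. The 10 top-ranked genes higher in ARKO were AI838599 (16.9), Lbh (11.3), Wfikkn2 (10.9), Enpp1 (6.92), Lag3 (5.74), Tppp3 (5.46), the ketohexokinase gene Khk (5.04), Ifitm1 (3.98), Pgr and Igfbp6. Those lower were Alpl with 2 and 178 UMIs (0.0115, 0.00138 to 0.0420), Tph1 with 2 and 75 UMIs (0.0272, 0.00323 to 0.102), Susd3 (0.0361), the nerve growth factor receptor gene Ntrk1 (0.0751), Asic4 (0.0839), Cyb561 (0.0849), Fbn2 (0.102), Acta1, Tnnc2 and Ckm. With each cell thinned the ratios of AI838599, Enpp1, Khk and Ntrk1 were 44.3, 4.12, 8.29 and 0.0480. Alpl stood at 0.0306 with new clusters and 0.00907 without likely doublets, and Tph1 at 0.0216 as a mean over cells. Beside these groups, dissociation stress genes were higher in 7 and lower in 0 of 20 (Hspa1a 2.5, percentile 98.67), and mitochondrially encoded genes lower in 6 and higher in 2 of 13 (median −0.65, percentile 0.215).

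**Figure D3:**
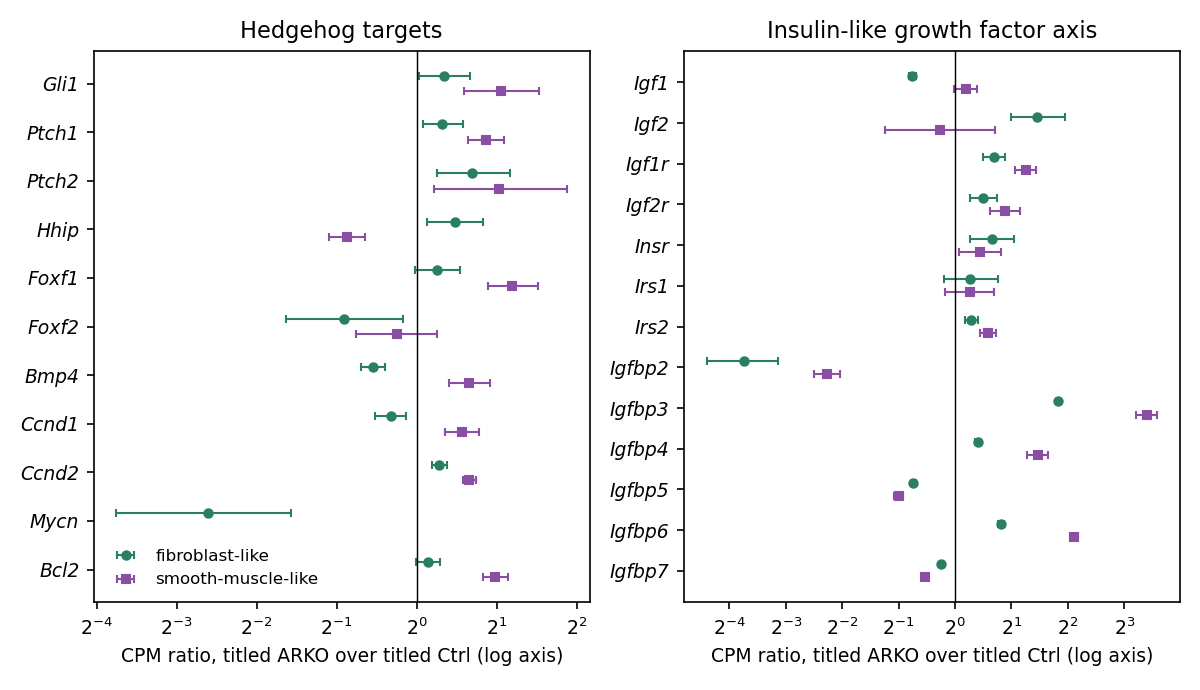
Ratios of CPM, library titled ARKO over library titled Ctrl, on a log axis for hedgehog targets and insulin-like growth factor genes in fibroblast-like and smooth-muscle-like cells, with points for ratios and lines for conditional exact 95% intervals (counting error only). The ratios of Gli1 are 2.07 in smooth-muscle-like and 1.27 in fibroblast-like cells. The smooth-muscle-like Igfbp3 ratio has a Ctrl level (36.2 CPM) no higher than that of T- or NK-like cells (37.0 CPM), so its size is uncertain.

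Basal-like cells (1380 in ARKO and 1471 in Ctrl, with 9650463 and 13865183 UMIs) had higher Shh in ARKO. Shh, a hedgehog ligand gene, stood at 67.5 CPM in ARKO and 19.98 CPM in Ctrl (3.38, 2.93 to 3.90), and its ratio was 1.94 (1.39 to 2.71) in cluster 3 and 2.70 (1.78 to 4.14) in cluster 6. The basal-like list of ligands and pathway parts that holds Shh had 2 higher and 2 lower of 10 (percentile 50.2), and hedgehog targets had 1 higher and 1 lower of 6. Insulin-like growth factor genes of basal-like cells had 4 higher, Igfbp6 (4.57), Igf1r (2.10), Irs2 (1.59) and Igfbp3 (1.51), and 1 lower, Igfbp5 (0.439), of 12, with a median of 0.39 at percentile 97.93. Igfbp3 stood at 46.9 and 31.1 CPM in ARKO and Ctrl basal-like cells, below the 181 and 37.0 CPM of T- or NK-like cells in the same libraries. The largest top-ranked ratio was that of Chac1, an enzyme gene of glutathione breakdown, at 61.0 and 2.88 CPM (21.2, 15.3 to 29.9). Flrt1 (8.66), the stress-induced pseudokinase gene Trib3 (7.94), Tmem86a (6.62), Pim1 (5.12), Sphk1 (4.89), Ddit4 (4.44), the metallothionein gene Mt1 (4.23) and Stat3 (4.06) were also higher. So was Aqp3 (4.67), a water channel gene that also leads clusters 0 and 12.

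Genes lower in ARKO basal-like cells included Bpifb5 with 3 and 228 UMIs (0.0189, 0.00387 to 0.0559), the neurotrophin receptor gene Ntrk2 (0.0701), Cck (0.158), Sardh (0.173), Spsb4 (0.180), Vcan (0.196) and the chemokine gene Cxcl10 (0.251). The Wnt inhibitor gene Wif1 (0.176) was lower too, with 21.6% of its Ctrl UMIs in 3 cells. With each cell thinned the ratios of Wif1, Bpifb5, Spsb4 and Tmem86a were 0.0281, 0.0420, 0.339 and 4.12. Matrix genes had 4 higher (Col6a3 9.0, Lum 5.06) and 7 lower (Eln 0.245, Col4a1 0.285) of 23, with a median of −0.06. Before subtraction the median was 0.01 and the mean −0.08, and the median was −0.43 as a mean over cells. Lum also leads the fibroblast-like cluster 7. It stood at 9.84 and 1.95 CPM in basal-like cells, below the 64.5 and 22.2 CPM of T- or NK-like cells. Col6a3 stood at 24.7 and 2.74 CPM, against 15.8 and 15.9 CPM there, and the source of neither was tested. Cluster 0 held 93.0% of these cells in ARKO and 93.1% in Ctrl. The new basal epithelial clusters, made without integration, held 1273 ARKO and 193 Ctrl cells, 101 and 1318, and 27 and 96. A different mix of basal-like states is therefore not separated from a difference within a state. Dissociation stress genes were higher in 8 and lower in 1 of 20 (Socs3 3.78, Hspa1b 2.17, Fos 2.12 and Atf3 0.619), with a median of 0.41 at percentile 99.22. Mitochondrially encoded genes were lower in 9 and higher in 1 of 13, with a median of −0.77 below all random lists.

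Clusters 3 (395 and 1149 cells) and 6 (301 and 577 cells) both had higher keratin and progenitor list medians in ARKO. In cluster 3, with median depths of 23768 and 15538 UMIs, the list had 6 higher and 3 lower of 17, with Psca at 7.05 (5.73 to 8.74), Ly6d at 2.75 (2.56 to 2.96), Krt5 at 0.630 and Prom1 at 0.452. In cluster 6, with median depths of 26256 and 20175 UMIs, it had 3 higher and 0 lower of 17, namely Psca at 3.45 (3.22 to 3.70), Ly6d at 3.34 and Krt17 at 2.56. In cluster 6 31.3% of the Psca and 46.0% of the Ly6d UMIs of ARKO lay in 3 cells. Medians lay at 0.38 and 0.36, at percentiles 100 and 99.99. The water channel gene Aqp8 stood at 38.2 (26.4 to 57.1) in cluster 3 and 5.82 (4.84 to 7.03) in cluster 6, with 24.0% and 37.2% of its ARKO UMIs in 3 cells of each. As a mean over cells the Aqp8 ratio in cluster 3 was 20.6. Matrix genes were lower in 15 and higher in 3 of 25 members in cluster 3 (Col4a2 0.197, Col4a1 0.202), with a median of −0.72 below all random lists. Before subtraction that median was −0.79, and it was −1.40 with each cell thinned. Antigen presentation genes were lower in 4 of 8 there (H2-Ab1 0.464, Cd74 0.473), with a median of −0.45 at percentile 0.01. Both genes also lead the myeloid-like cluster 10. In cluster 3 they stood at 4.37 and 9.42 CPM and at 27.5 and 58.1 CPM, against 18.2 and 55.0 CPM and 57.2 and 173 CPM in T- or NK-like cells. In cluster 6 Cd74 stood at 20.6 and 20.8 CPM. The source of this RNA was not tested.

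Secretory genes of cluster 6 had 4 higher and 4 lower of 11, with Msmb at 4.21, Defb50 at 3.02, Pbsn, which encodes probasin, at 2.54, and Sbp at 0.429 (percentile 79.7). The median of the list was 0.18, or −0.01 before subtraction, and the latter was 1.12 with each cell thinned and 0.63 with members of at least 100 UMIs. Msmb and Sbp also lead the cluster, and 24.1% of the Msmb UMIs of ARKO lay in 3 cells. Top-ranked genes lower in ARKO cluster 6 included Smr2 (0.0757, with 30.1% of Ctrl UMIs in 3 cells), Cited1 (0.0956), Crabp1 (0.132), the prostaglandin D receptor gene Ptgdr (0.143) and Dazl (0.143). In cluster 3 those lower included Golga7b with 3 and 126 UMIs (0.0500, 0.0102 to 0.150), Reg3g (0.263), Odam (0.277) and the replication gene Mcm6 (0.371). With each cell thinned the ratios of Smr2, Cited1, Ptgdr and Dazl in cluster 6 were 0.191, 0.150, 0.282 and 0.679, and those of Golga7b, Odam and Reg3g in cluster 3 were 0.253, 0.443 and 0.177. Dissociation stress genes were higher in 7 and lower in 0 of 20 in each of these clusters, with medians of 0.50 and 0.34. The contractile median of cluster 3, −0.53 before subtraction, was 0.0552 with each cell thinned.

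RNA of seminal vesicle secretory genes was higher in Ctrl in every class outside the seminal-vesicle-like cluster. Svs4 stood at 23.9 CPM in ARKO and 508 CPM in Ctrl fibroblast-like cells, a ratio of 0.0471. Over the classes outside the seminal-vesicle-like cluster the Svs4 ratio ran from 0.0296 in myeloid-like to 0.0736 in pericyte-like cells. Within the seminal-vesicle-like cluster Svs4 stood at 46143 and 101748 CPM, a ratio of 0.454.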

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

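The tests on Ar, Mki67 and seminal vesicle RNA weighed here were all chosen after those results had been seen, and the condition on counting error for seminal vesicle RNA was added after the value of its test was known. In addition, 4 hedgehog genes stood out because their ratio of the library titled ARKO over the library titled Ctrl was at least 1.5-fold above 1 in some classes and below it in others. Ccnd2 had 1.58 in smooth-muscle-like cells and 0.382 in cluster 6. Cdon had 2.78 in fibroblast-like cells, 1.62 in basal-like cells and 0.536 in cluster 6. Its basal-like ratio rested on 44 UMIs in ARKO and 39 in Ctrl (1.03 to 2.56). Evc had 1.72 in smooth-muscle-like cells, 0.619 in basal-like cells and 0.227 in cluster 3, the last from 4 and 37 UMIs (0.0588 to 0.632). Gas1 had 1.66 in cluster 3 and 0.628 in smooth-muscle-like cells. In cluster 3 Gas1 stood at 6.29 and 3.80 CPM, under 0.2 of the 260 and 414 CPM of smooth-muscle-like cells. Free RNA was not excluded there. The differences between classes were not tested, since each group has 1 library.

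Ar was lower in the fibroblast-like and smooth-muscle-like cells of the library titled ARKO, which the genotype field calls normal. A larger share of cells from clusters of low Ar is argued against as the whole account. Over the 5 fibroblast-like and smooth-muscle-like clusters the highest upper bound of the ratio was 0.804, below 1. These clusters may pool cell states, as 8 of 13 new fibroblast or smooth muscle clusters had at least 90% of cells from 1 library. A shift towards states of low Ar within a cluster therefore stays open. A loss confined to cells with EGFP UMIs is argued against too, since in cells with no EGFP UMI the highest upper bound was 0.583. The highest upper bound over both classes was 0.539, which would go with the titles if the 3' tags of Ar report the deletion, but the deleted part is not named, so an exchange of names between title and genotype field stays open. Loss of Ar in Gli1-expressing cells, a difference between the mice and a difference between the preparations remain open as well, because each group is 1 library.

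Cells with an Mki67 UMI were fewer in epithelium and stroma of the library titled ARKO. Its lower median depth is argued against as the whole account: at 2000 UMIs per cell the upper bound of the epithelial share was 1.12% in ARKO, below the lower bound of 3.54% in Ctrl. Likely doublets in Ctrl are argued against, because without them the highest upper bound of the ratio was 0.235. One equal loss of Mki67 in all cell types is argued against by myeloid-like cells, where the lower bound of the ratio was 0.897, above the epithelial upper bound of 0.284, but the proliferation list as a whole was lower in myeloid-like cells too (0.770, 0.717 to 0.828), so a loss of unequal size in all types stays open. A biological difference between the genotypes may remain, but the stage of the 2 mice of each library, the part of the gland taken and the preparation were not separated from the group.

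Seminal vesicle secretory RNA was seen in classes outside the seminal-vesicle-like cluster and was higher there in the library titled Ctrl. A candidate explanation is free RNA of seminal vesicle cells, which would keep Svs5 and Svs4 in one ratio in every class of a library. Over the classes with at least 50 Svs4 UMIs, the ratio departed from that of the seminal-vesicle-like cluster by at most 1.36 times, in cluster 6 of Ctrl (1.15 against 1.57). That was beyond counting error, as it was in 9 of 13 classes of Ctrl and 0 of 5 of ARKO, so the explanation stays open, with neither 1 source at the ratio of the captured cells nor another source shown. No biological explanation was tested.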

How the results depend on the processing

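Chosen after the data were seen were single clusters, EGFP classes, the addition of cluster 14 or 18, the share outside the seminal-vesicle-like cluster and the Mki67 alternatives. No paired analysis was possible because each group has 1 library, and leaving out a library is not possible for the same reason. New clusters gave no value for clusters 3 and 6. List medians were compared with their values under an alternative 897 times. Of these, 865 stayed within the interval of the median, 23 moved outside it and 9 reversed. For single genes the counts were 635, 116 and 1 of 752 comparisons. The widths of the intervals of list medians are not given, and a median that stayed within its interval could still shift far or change sign. The hedgehog target median of cluster 3 (5 measured members), −0.04, counted as staying at 0.78 with members of at least 1 UMI. So did the secretory median of cluster 6, −0.01, at 1.12 with each cell thinned. A sign change counted as reversed only for medians outside the middle of random lists. Hedgehog targets of smooth-muscle-like cells ran from 0.61 to 0.79 (log2), contractile genes there from −0.83 to −0.72, and in fibroblast-like cells insulin-like growth factor genes from 0.28 to 0.52 and matrix genes from −1.01 to −0.57. Where no cause is named, the cause was not tested. Depth limited genes of few UMIs, such as Alpl in smooth-muscle-like cells (2 and 178 UMIs), whose ratio had an interval from 0.00138 to 0.0420. Of 106 pairs of named gene and class, 32 moved by over 1.5 times under some alternative, and 1 of these, Uchl1, changed direction.

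The Ar log2 ratio was −1.01 in fibroblast-like cells, against −1.12 with each cell thinned, −1.20 in cluster 1 and −0.83 in cluster 2. In smooth-muscle-like cells it was −1.18, against −1.36 thinned, −0.54 in cluster 4 and −1.61 in cluster 5. Thinning gave 0.0837 in basal-like cells and 0.38 in cluster 3, and a median-of-ratios size factor gave −0.19 in cluster 6. Uchl1 in fibroblast-like cells reversed to 0.0253 with new clusters, and 87.5% of its Ctrl UMIs lay in 3 cells.

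Among medians outside the middle 95% of random lists, those reversed were steroid receptor genes in smooth-muscle-like cells (−0.30 thinned, −0.21 with members of at least 100 UMIs), proliferation there (0.0498 and 0.37 under the same settings), keratins there (0.0396 with new clusters), contractile genes in cluster 3 (0.0552 thinned) and transforming growth factor beta and bone morphogenetic protein genes in cluster 6 (−0.0228 without the top 10% by mitochondrial share, −0.0861 with members of at least 1 UMI and −0.0373 with at least 100). Medians inside that middle changed sign 92 times, over 38 medians, such as the transforming growth factor beta list in smooth-muscle-like cells (−0.12 with new clusters) and antigen presentation in fibroblast-like cells (−0.0378 with members of at least 100 UMIs). Moved medians in fibroblast-like cells were proliferation (−3.08 with new clusters, −3.38 with cluster 14) and contractile genes (−0.43 without the top 10% by mitochondrial share, −0.99 with new clusters, −1.17 with cluster 14). A median-of-ratios size factor moved androgen response to −0.0453 in fibroblast-like cells and 0.0321 in cluster 6, ribosomal proteins to 0.32 in fibroblast-like cells, 0.0817 in cluster 3 and 0.28 in cluster 6, and in cluster 6 Wnt to 0.45 and interferon response to 0.00131. A total without mitochondrial, ribosomal, haemoglobin and secretory genes moved androgen response to −0.13 in basal-like cells and −0.0930 in cluster 6, and ribosomal proteins to −0.36 and 0.16. Thinning moved matrix genes in cluster 3 to −1.40, and in cluster 6 androgen response to −0.0922 and contractile genes to −0.62. The mean over cells moved androgen response in cluster 6 to −0.0946 and contractile genes in cluster 3 to −0.17. Without likely doublets contractile genes stood at −0.81 in cluster 3 and −0.59 in cluster 6.

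Differences in share (ARKO minus Ctrl, percentage points) kept their direction. The epithelial difference of −21.6 became −21.3 without the top 10% by mitochondrial share, −21.4 without the bottom 10% of UMI totals, −23.1 without leucocytes and −24.5 outside the seminal-vesicle-like cluster. The stromal difference of 28.1 became 27.5, 29.0 and 26.5 under the last 3 of these. That of seminal-vesicle-like cells, −4.85, became −5.44 without the top 10% by mitochondrial share. The Mki67 ratio in epithelium, 0.252, became 0.205 without likely doublets and 0.191 thinned, and in stroma 0.122 became 0.0829 thinned. Of the 20 top-ranked genes of a class, a minimum of 200 UMIs kept 15 in fibroblast-like cells, 12 in smooth-muscle-like cells, 18 in basal-like cells and 13 in each of clusters 3 and 6. With no filter on free RNA, 14, 12, 11, 5 and 7 were kept.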

Other observations

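Notch genes of basal-like cells and cluster 3 held several members higher in the library titled ARKO. The ligand gene Dll1 had a ratio of 2.95 in basal-like cells and 2.58 in cluster 3, and the target gene Hes1 2.32 in basal-like cells. Of 10 measured members in basal-like cells 4 were higher and 0 lower (percentile 69.6), and of 12 in cluster 3 there were 3 higher and 1 lower (percentile 96.6). Cluster 6 had 1 higher and 2 lower of 10. Fgfr3, a fibroblast growth factor receptor gene, had 2.04 in basal-like cells and 1.92 in cluster 6, while Etv4 had 0.291 in basal-like cells. The fibroblast growth factor list had 1 higher and 2 lower of 12 in basal-like cells, and 1 higher and 5 lower of 12 in cluster 6. The inhibin subunit gene Inhbb had 4.57 and Bmp7 0.537 in basal-like cells. In cluster 6 the Wnt target gene Axin2 had 2.06, but the Wnt list had 1 higher and 1 lower of 11, with a median 0.44 above the median gene (percentile 96.6) and, before subtraction, a median of 0.26 and a mean of 0.02. Complement factor gene Cfh had 4.39 and the chemokine gene Ccl2 0.213 in basal-like cells.

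Genes of the mitochondrial genome did not move together. In fibroblast-like, smooth-muscle-like and basal-like cells and clusters 3 and 6, mt-Nd4l had ratios of 1.94, 2.70, 2.10, 2.26 and 2.27, while mt-Co3 had 0.457, 0.549, 0.476, 0.695 and 0.677. The ratios of mt-Atp8 were 1.5, 1.81, 1.41, 1.99 and 1.64, and those of mt-Nd1 0.485, 0.489, 0.546, 0.777 and 0.729. Hist1h2al, annotated as a processed pseudogene, had 76 UMIs in ARKO and 1 in Ctrl in cluster 3, a ratio of 159.7 (27.8 to 6389), and 152 and 4 UMIs in cluster 6, a ratio of 60.0 (22.9 to 223). With each cell thinned these ratios were 36.1 and 24.0, and as a mean over cells 219 and 35.4. No explanation of these values was tested.

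New clusters of the cells, made without integration of the libraries, were often of 1 library. Of 30 such clusters 11 had at least 90% of their cells from 1 library, 8 of them fibroblast or smooth muscle clusters, against 2 of the authors' 19 clusters.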
